A study of Caenorhabditis elegans with 4 samples.

How the data were processed

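ChIP-seq was performed on worms of strain OP184, in which LIN-15B carries a GFP tag. Per the labels' protocols, synchronized worms were raised on bacteria at 20 °C to the L3 stage. Crosslinking used formaldehyde at 2%, stopped by Tris at 100 mM, and chromatin was sheared by sonication. Tagged chromatin was recovered with an affinity-purified goat antibody against GFP, and Illumina libraries were made after selection of fragment size on a gel. The protocol text speaks of embryos at the lysis step, while the sample labels give L3. There were 4 samples in 2 groups, immunoprecipitated DNA (2 samples) and input DNA (2 samples), numbered as replicates 1 and 2 in the labels and assigned by their descriptions. The labels tie the replicate numbers to separate extractions.

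The data used were 1 list of peaks for the whole series, named as combined by its authors. Per the file headers the coordinates are on WormBase WS180, and each line names PeakSeq as its source. The aligner, the read filters, the PeakSeq version and settings, and how the replicates were combined are not given in the sources used here. Each line gives the first and last base of a region, counted from 1, and a q-value that the authors deposited both as the score and as an attribute; the 2 entries were equal in all 4141 lines to a relative tolerance of 1e-09. The q-value of a line multiplied by its place in the list never fell from one line to the next, and 1640 of 4140 neighbouring lines were tied in this product (to a relative tolerance of 1e-06). This is the order that p-values divided by their rank would have without a monotone adjustment. The q-value of 1698 lines was below that of the line before. No read counts, fold enrichments or summits were used here, and the depth of the libraries is unknown. Because a q-value depends on the reads in a region as well as on its enrichment, strength is not occupancy.

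The analysis was written in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and the plots in matplotlib 3.10.9. Strength was -log10 of the q-value, width was the number of bases from first to last, and position was the midpoint. No peak was left out. As no chromosome lengths of WS180 were used here, each chromosome's span ran from its first to its last peak. Numbers of peaks per chromosome and in the central section were compared with the share of span by exact binomial tests, two-sided, adjusted by Benjamini-Hochberg over 6 chromosomes, with Clopper-Pearson intervals for shares and exact Poisson intervals for densities. Intervals cover counting error only. Spacing was compared with 1000 uniform placements of the same number of midpoints on each chromosome, one-sided. These placements do not keep a minimum distance between peaks. Medians of strength were compared by permutation with 100000 resamples (10000 for comparisons of single chromosomes or classes), with percentile bootstrap intervals from 10000 draws. The main tests and the rule for naming the 20 strongest peaks by q were fixed before the data were examined; the comparisons of single chromosomes' strength, of wide peaks, of outer sections, of windows and of close pairs by strength were added afterwards. The rule broke ties by a further strength value, which the list does not hold, but no ties in q occurred among these peaks.

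The tests were tried on 100 simulated lists of 4141 peaks with no effect, in which the X share was called in 1%, the central share of chromosome II in 3%, close spacing in 1% and X strength in 7%. In 100 lists with X density lowered, the centre of II enriched, close pairs added and X strength lowered, the same tests called 100%, 98%, 100% and 92%. On the simulated lists the spacing and X strength tests used fewer placements and resamples than on the real list. Their rates are therefore approximate for the tests reported. The planted effects were not matched in size to those observed. The centre of II was given a density of 1.5, while its observed share was 1.14 times that expected. The 98% is therefore not the rate for the observed effect. The lists with no effect lacked close spacing, so their rates may not hold for peaks as clustered as those observed.

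The reference gene table supplied, of assembly WBcel235, is on another build than the peaks. Only the number of its protein-coding genes on each chromosome was used, and none of its coordinates. The planned comparisons of peaks with gene starts, with gene lists fixed in advance and with sequence motifs need an annotation or genome of WS180 and were not made here. For the same reason the lin-15B and unc-119 loci, present in the transgene, were not examined. Alternatives covered the stronger 2070 peaks, the strongest 1000 peaks, merging of regions within 1 kb, gene number as expectation, a wider central section, a distance of 5 kb, and removal of the widest regions. Chosen after seeing the data were removal of the narrowest regions, the weaker 2071 peaks alone, extension of the spans, permutation of 500 kb windows and the product of q and rank as strength.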

Results

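Binding of LIN-15B, a THAP-domain protein of the synMuv B class, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole hermaphrodites of Caenorhabditis elegans at the L3 larval stage. SynMuv B proteins are known to restrain vulval induction and to keep germline genes silent in somatic cells. The worms, of strain OP184, carried a lin-15B transgene tagged with GFP and 3xFlag and an unc-119 rescue marker, and were grown at 20 °C. Of the 4 libraries, 2 were immunoprecipitated with a goat antibody against GFP and 2 were input DNA, so that each of the 2 replicates had its own input. The question was where in the genome the tagged protein was bound at this stage. The result is 1 list of peaks for the whole experiment, with a position and a q-value for each peak and no value for either replicate. Read depth per library was therefore unknown, no spread between replicates could be computed, and every interval and p-value below describes the placement of peaks within this list only.

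The list held 4141 peaks on the 5 autosomes and X. They covered 1.65 Mb, or 1.65% of the 99.95 Mb between the first and last peaks of the chromosomes, at 41.4 peaks per Mb. Most peaks were narrow: the median width was 367 bp, with quartiles at 297 and 450 bp. At the extremes, 58 peaks exceeded 1000 bp and 36 were under 50 bp, 4 of which spanned a single base. Peak strength, taken as -log10 of the authors' q-value, ranged from 2.00 to 148 with a median of 6.30. A q-value under 0.001 was reached by 3234 peaks (78.1%), under 1e-10 by 1494 (36.1%), under 1e-50 by 271 (6.54%) and under 1e-100 by 45 (1.09%).

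The 20 strongest peaks, with -log10 q of at least 119.3, lay on every chromosome, 7 of them on chromosome IV and 1 on X. Coordinates are those of WormBase WS180, and which gene lies at each position was not analysed here. The strongest peak of the list spanned 14685477 to 14686095 on chromosome V, with -log10 q of 148. It was followed by the peak at 10758859 to 10759459 on chromosome III, with 146, and by that at 4749831 to 4750310 on chromosome IV, with 143. The other chromosome IV peaks of this set lay at 7084707 to 7085210, 13240296 to 13240899, 1420028 to 1420584, 14032417 to 14034588, 3294170 to 3295026 and 654677 to 655218. Chromosome III held further peaks at 7162193 to 7162713, 2785672 to 2786312 and 5172415 to 5172882. Chromosome II held peaks at 10563215 to 10563754, 8561128 to 8561599 and 7104873 to 7105373. Chromosome I held peaks at 10553663 to 10554237, 14469087 to 14469544 and 13663117 to 13663629. The second peak of the set on chromosome V lay at 104315 to 104959, and the only one on X at 5840831 to 5841508, with -log10 q of 123. Their widths ran from 458 to 857 bp, apart from the chromosome IV peak at 14032417 to 14034588, which was 2172 bp wide. Of these 20 peaks, 5 lay in the central 33.3% of their chromosome's span.

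LIN-15B peaks were unevenly divided among the chromosomes. Chromosome III was the most densely bound, with 809 peaks or 58.9 per Mb (95% exact Poisson interval 54.9 to 63.1), 1.42 times the number its share of the span would give. Chromosome IV followed with 829 peaks at 47.6 per Mb (44.4 to 50.97), 1.15 times its share. X was the most sparsely bound, with 532 peaks at 30.2 per Mb (27.7 to 32.9), 0.729 times its share, and chromosome V came next with 691 peaks at 33.1 per Mb (30.7 to 35.7), 0.799 times its share. In exact binomial tests, two-sided and adjusted by Benjamini-Hochberg over the 6 chromosomes, the excess on III (adjusted p = 5.2e-24) and IV (adjusted p = 2.3e-05) and the shortfall on X (adjusted p = 1.6e-16) and V (adjusted p = 2.2e-11) passed the threshold of 0.05. Chromosomes I (664 peaks, 1.06 times, exact binomial adjusted p = 0.10) and II (616 peaks, 0.975 times, exact binomial adjusted p = 0.52) did not. Among the strongest 1000 peaks both were called above their share by span, I at 1.22 times (exact binomial adjusted p = 0.0061) and II at 1.17 times (exact binomial adjusted p = 0.033). The exact binomial tests treat peaks as independent. When whole windows of 500 kb were permuted instead, the same 4 chromosomes passed, with adjusted p between 3e-05 and 0.021 in the permutation test. That permutation treats neighbouring windows as independent of each other. Likeness between them, which was not tested, would make these p-values too small.

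Against the number of protein-coding genes, the shortfall on X was not called. X carries 2730 of these genes, 13.7% of the total in the WBcel235 gene table, and held 12.8% of the peaks (95% exact interval 11.8% to 13.9%), a ratio of 0.940 (exact binomial adjusted p = 0.13). Chromosome V, which carries 4995 protein-coding genes, lay further below that expectation, at 13.8 peaks per 100 genes and 0.667 times its share (exact binomial adjusted p = 2.7e-37). Chromosome III remained the highest, at 30.6 peaks per 100 genes and 1.48 times its share (exact binomial adjusted p = 3.4e-29). Chromosome II, not called by span, fell below its share by genes (0.862 times, exact binomial adjusted p = 5.8e-05), and chromosome I lay above it (1.11 times, exact binomial adjusted p = 0.0039).

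**Figure D1:**
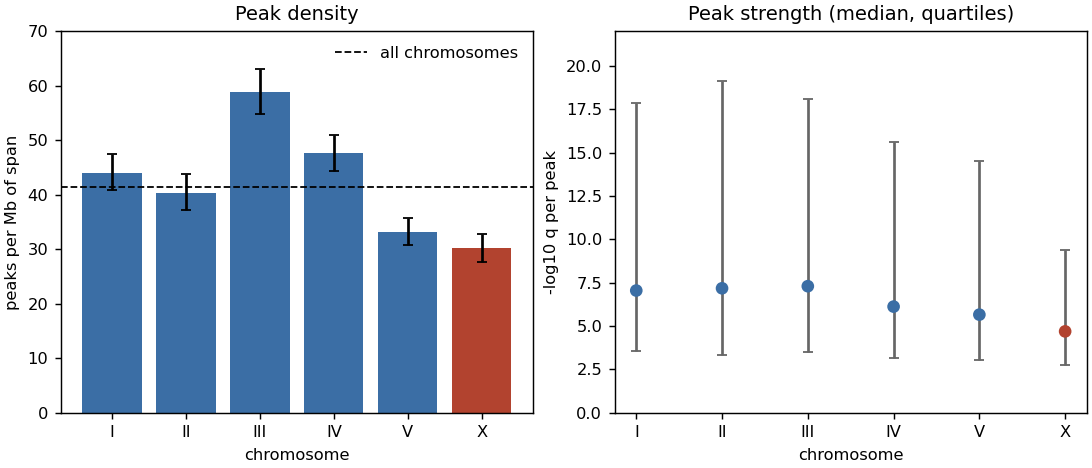
Left, LIN-15B peaks per Mb of span on each chromosome (bars, with 95% exact Poisson intervals) and the value over all chromosomes (dashed line, 41.4 per Mb); right, median -log10 q per peak on each chromosome, with bars from the lower to the upper quartile. X (red) had the lowest density, 30.2 per Mb, and the lowest median strength, 4.69, and chromosome III the highest of both, 58.9 per Mb and 7.30.

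Peaks on X were also weaker than those on the autosomes. Their median -log10 q was 4.69 (532 peaks) against 6.58 on the autosomes (3609 peaks), a difference of -1.89 (95% bootstrap interval -2.51 to -1.25, permutation test, two-sided, p = 0.00016). Peaks with q under 1e-50 made up 3.20% of the X peaks (17 peaks, 95% exact interval 1.87% to 5.07%) and 7.04% of the autosomal ones (254 peaks; Fisher's exact test, two-sided, p = 0.00046). Among the strongest 1000 peaks of the list X held 0.403 times its share by span, and within that set the difference in medians, -2.90, was not called (permutation p = 0.28). Chromosome III had the highest median strength, 7.30, against 6.14 over the other chromosomes (permutation test, adjusted over 6 chromosomes, p = 0.0063). Chromosomes I (7.05, adjusted permutation p = 0.046) and II (7.18, adjusted permutation p = 0.046) also lay above the other chromosomes. The others include the weaker X in each case, and no comparison with the other autosomes alone was made. Chromosomes IV (6.12) and V (5.66) were not distinguishable from the others (adjusted permutation p = 0.53 and 0.094).

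Stronger peaks were wider over the list, yet the median width was 364 bp on X and 367 bp on the autosomes, a difference that was not tested. Peaks wider than 1000 bp made up 3.01% of the X peaks (16 peaks, 95% exact interval 1.73% to 4.84%) and 1.16% of the autosomal peaks (42 peaks, 0.840% to 1.57%; Fisher's exact test, two-sided, p = 0.0023). Across all 4141 peaks, which are not independent replicates, width and -log10 q had a Spearman correlation of 0.682 and a Pearson correlation of 0.374, both with a permutation p of 1e-05, the smallest that the 100000 resamples can give. Width and q come from the same peak call, and q depends on the reads in a region. A positive relation can therefore arise from the calling itself, and the p-values do not bear on binding. The median -log10 q was 2.70 among peaks of up to 297 bp and 5.43 among those of 298 to 367 bp. It was 14.3 among those of 368 to 450 bp and little higher, 15.04, among those of 451 bp or more. None of the 36 peaks under 50 bp exceeded a -log10 q of 3.50.

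**Figure D2:**
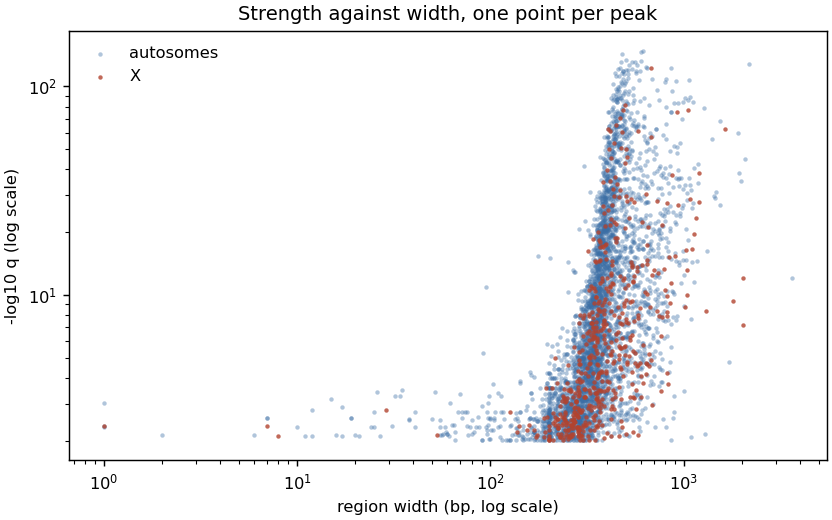
Strength (-log10 q, log scale) against region width (bp, log scale), one point per LIN-15B peak, for the autosomes (blue, 3609 peaks) and X (red, 532 peaks). Strength rises with width over the list (Spearman correlation 0.682), and the regions under 50 bp do not exceed 3.50. The median changes little from regions of 368 to 450 bp (14.3) to those of 451 bp or more (15.04).

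Along the chromosomes, central enrichment was clearest on chromosome V. There the central 33.3% of the span (6.96 to 13.9 Mb) held 286 of 691 peaks, 41.4% (95% exact interval 37.7% to 45.2%), at 41.1 peaks per Mb against 31.2 in the left section and 27.03 in the right (exact binomial test against 33.3%, adjusted p = 6.3e-05). With 500 kb windows permuted the call on V remained, but close to the threshold of 0.05 (adjusted permutation p = 0.047). Likeness between neighbouring windows, which the permutation ignores, could remove it. On chromosome II the central section held 38.0% (34.1% to 42.0%, exact binomial adjusted p = 0.045), a call lost when 500 kb windows were permuted (adjusted permutation p = 0.15). The central shares of chromosomes III (36.7%, adjusted p = 0.088), IV (34.3%, adjusted p = 0.70), I (33.1%, adjusted p = 0.93) and X (29.7%, adjusted p = 0.12) were not called different from 33.3% in the exact binomial test. That of III was called among the stronger 2070 peaks (1.19 times its share, exact binomial adjusted p = 0.021) and when the central 50% of the span was taken (1.11 times, exact binomial adjusted p = 0.0036). Differences between chromosomes in this share were not tested.

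The 2 outer sections differed in number of peaks on chromosomes II and IV. On chromosome II the left section held 139 peaks (27.4 per Mb) and the right 243 (47.8 per Mb), a 1.75-fold difference (exact binomial test, adjusted over 6 chromosomes, p = 6.9e-07). On chromosome IV the left section held 324 (55.8 per Mb) and the right 221 (38.1 per Mb), 1.47-fold (adjusted exact binomial p = 3.5e-05). On chromosomes I, III, V and X the difference was not called (adjusted exact binomial p between 0.093 and 0.32). These tests treat peaks as independent, and windows of 500 kb were not permuted for the outer sections. In windows of 500 kb the number of peaks ranged from 1 to 43, with a median of 20. The fullest was 2500001 to 3000000 on chromosome IV, with 43 peaks, 20 of them between 2600001 and 2700000. It was followed by 8500001 to 9000000 on chromosome III and 4000001 to 4500000 on chromosome IV, with 41 each. The emptiest was 17000001 to 17500000 on chromosome V, with 1 peak, and the next was 1500001 to 2000000 on chromosome II, with 5. In 1000 uniform placements, which kept each chromosome's number of peaks, single windows held between 2 and 51 peaks over all chromosomes. The fullest window lay within that range and the emptiest below it. No range was computed for single chromosomes. The highest count may have come from a denser one than IV, as windows held 30.0 peaks on average on III and 23.8 on IV. The longest stretches without a peak lay at 16966241 to 17363453 on chromosome V (397 kb) and 1663854 to 2058980 on chromosome II (395 kb). In 1000 uniform placements of the same number of peaks the longest stretch on any chromosome averaged 246 kb and reached 468 kb. Here too no value was computed for chromosomes II or V alone. The ratio of variance to mean over the 191 windows was 3.04, above the highest value in these placements, 2.42.

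**Figure D3:**
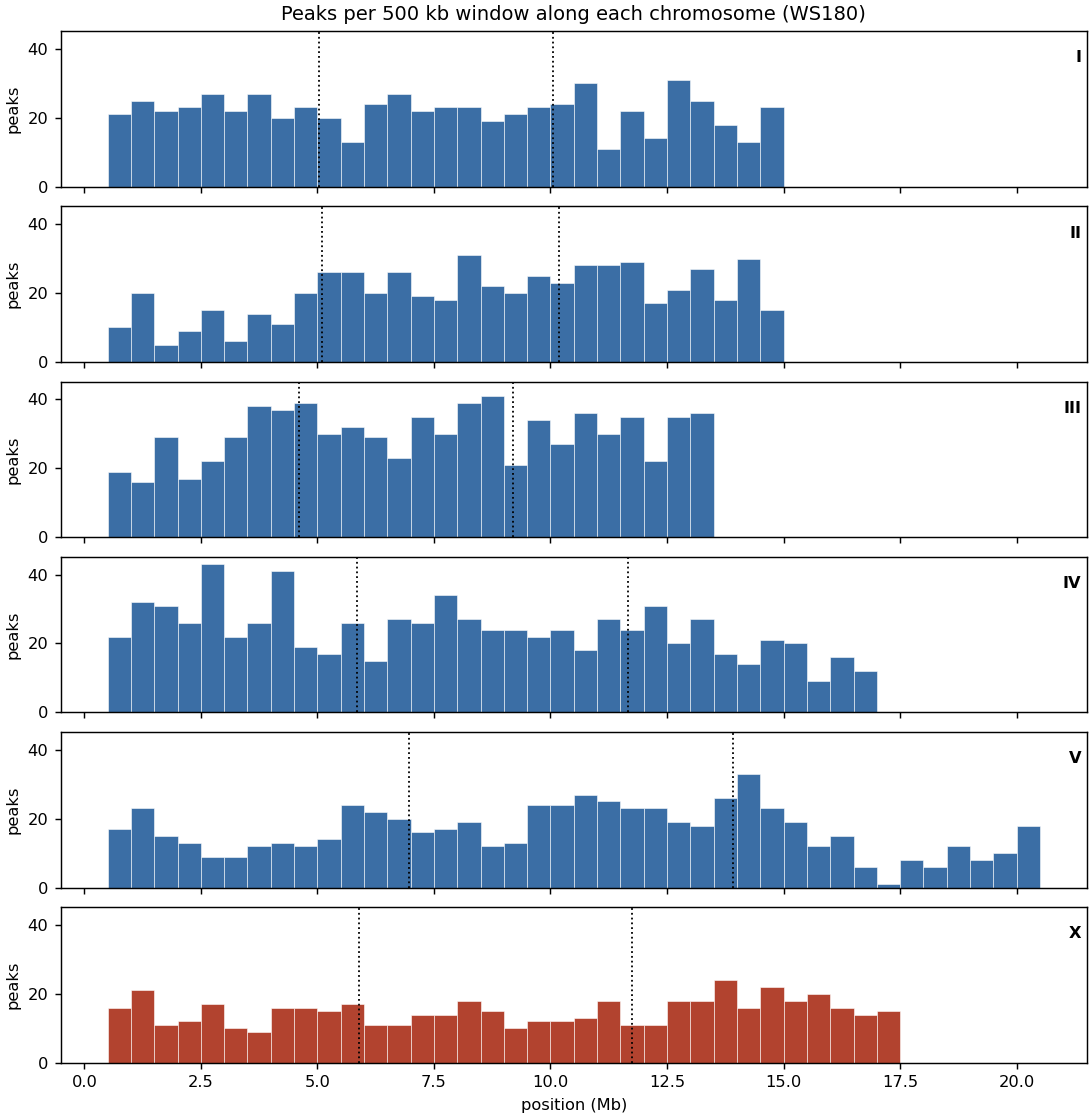
LIN-15B peaks per 500 kb window (bars) along each chromosome, by position in Mb of WS180, with dotted lines at the borders of the central section; windows reaching beyond the first or last peak are not drawn. Peaks are sparse on the left of chromosome II and the right of chromosome V, where one window holds 1 peak, and dense over chromosome III and the left of IV, where one window holds 43.

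Neighbouring peaks lay closer together than uniform placement would give. Midpoints of 455 of 4135 neighbouring pairs were within 2 kb, against 344 ± 16.9 (mean and SD of 1000 placements), a ratio of 1.32 (permutation of positions, one-sided, p = 0.001, the smallest these placements can give). The excess was in pairs 1 to 2 kb apart, 312 against 169, and 2 to 5 kb apart, 653 against 462, while pairs within 1 kb numbered 143 against 175. No 2 peaks had edges closer than 202 bp. By chromosome the ratio within 2 kb was 2.06 on V (91 pairs) and 1.56 on IV (118 pairs), both with an adjusted permutation p of 0.003. The ratios on I (1.25), II (1.11), III (1.08) and X (0.826) did not pass (adjusted permutation p between 0.066 and 0.87). Differences between chromosomes in this ratio were not tested. Close pairs were more frequent among weaker peaks: the 2071 weaker peaks held 140 among themselves and the 2070 stronger ones 94. This difference of 46 exceeded that obtained when strengths were shuffled within chromosomes (-3.50 ± 14.5, mean and SD, two-sided permutation p = 0.001, the smallest possible). Taken alone, the stronger 2070 peaks had a ratio of 1.03 (permutation p = 0.37) and the strongest 1000 one of 1.34 (permutation p = 0.065), and merging regions within 1 kb, which removes close pairs, gave 0.538.

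**Figure D4:**
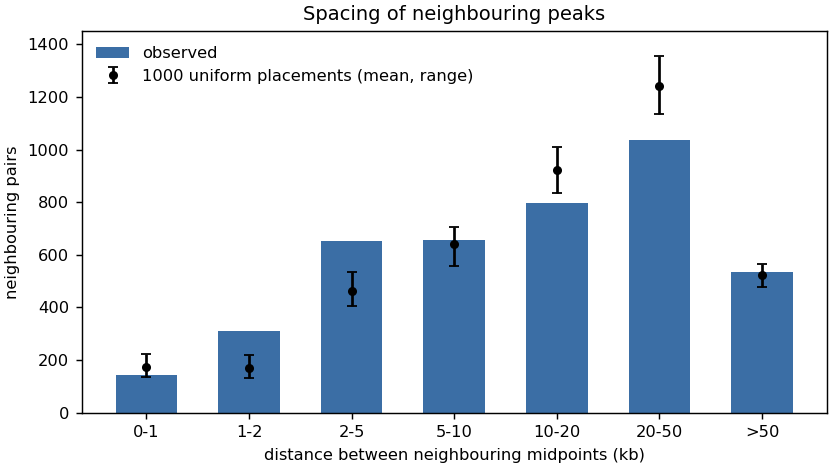
Number of neighbouring peak pairs (bars) by the distance between their midpoints in kb, with the mean and range of 1000 uniform placements (points and whiskers). The bars exceed the range at 1 to 2 kb (312 pairs) and 2 to 5 kb (653 pairs) and fall below it at 10 to 20 kb (798 pairs) and 20 to 50 kb (1037 pairs).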

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

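The alternatives with windows permuted, extended spans, the product of q and rank, the weaker 2071 peaks and narrow regions left out were chosen only after seeing the data. No paired analysis was possible because the list holds no value for either replicate, and leaving out a replicate could not be done for the same reason. Alternatives for gene starts, gene lists and motifs, and that with a further strength value, were not run. Of 87 alternatives, 67 were unchanged in direction and side of the threshold, 7 lost a call, 6 gained one and 7 turned direction. The 67 include the numbers of peaks left without the widest (4136) or the narrowest regions (4105), which have no test. They also include values called neither before nor after, so the tally is no measure of robustness. With gene number as the expectation the shortfall on X was 0.940 and not called, because X's share of genes is smaller than its share of span; under the other alternatives it was called (0.403 to 0.759). The excess in the centre of chromosome II (1.14) was not called among the stronger 2070 peaks (1.17), the strongest 1000 (1.13) or with 500 kb windows permuted (1.17). That of chromosome III (1.10) was called among the stronger 2070 peaks (1.19) and with the central 50% of the span (1.11). The close spacing (1.32) was not called among the stronger 2070 peaks (1.03) or the strongest 1000 (1.34), and fell to 0.538 once regions within 1 kb were merged, since merging itself removes such pairs. Among the weaker 2071 peaks it was 1.63. The lower strength on X was not called among the strongest 1000 peaks (-2.90). The share of chromosome II turned from 0.975 to 1.17, called, among the strongest 1000 peaks and was called low against gene number (0.862). That of chromosome I (1.06) was called among the stronger 2070 peaks (1.17), the strongest 1000 (1.22) and against gene number (1.11). X held 0.578 times its share by span among the stronger 2070 peaks and 0.403 times among the strongest 1000. Low shares of X raise those of the autosomes on average, and no test among the autosomes alone was made. Values near 1 that were called neither before nor after also crossed it: the share of II became 1.04 among the stronger 2070 peaks, and the central share of I (0.994) became 1.08 among the stronger 2070, 1.06 among the strongest 1000 and 1.01 with the central 50%, and that of IV (1.03) 0.920 among the strongest 1000. Except for gene number and merging, the cause was not tested. The unknown read depth limits any statement on regions without a peak, which fell short of the authors' threshold and may still be bound.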

Other observations

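The tests of the chromosome arms, of width at like strength, of the strength of peaks with a close neighbour and of strong X peaks against gene number were chosen only after the result was seen. The comparisons of X with gene number and among the stronger 2070 peaks were set in advance as alternatives, and were used to weigh explanations only after their values were seen. Those of split regions, of local density and of likeness between neighbours were set down before their results were known.

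At like strength, LIN-15B peaks on X were wider than autosomal ones. When all peaks were divided by -log10 q into 5 classes of equal size, the median width on X exceeded that on the autosomes in each class, by 20 bp in the weakest (269 against 249 bp), 39 bp, 32 bp, 50 bp and 37.5 bp in the strongest (490.5 against 453 bp; permutation tests, adjusted p between 0.0005 and 0.034). The share of X among the peaks fell over the same classes from 17.7% in the weakest, near its 17.6% of the span, to 6.76% in the strongest.

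The widest regions were not all strong. The widest of all, 3638 bp, was the last peak of chromosome I, at 15064001 to 15067638, with a -log10 q of only 12.1. X held 2 of the 5 regions over 2 kb, at 3114650 to 3116675 (-log10 q 7.18) and 15740894 to 15742915 (12.1), II held one at 11634001 to 11636065 (44.7), and IV one at 14032417 to 14034588 (128), among the 20 strongest peaks. The peaks with a neighbour within 2 kb (839) had a lower median strength than the other 3302, 5.40 against 6.48, a difference of -1.08 (95% bootstrap interval -1.62 to -0.337, permutation p = 0.0065).

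The shortfall of peaks on X was weighed against the number of genes and the threshold of the list. Fewer protein-coding genes on X may account for the number of peaks, since against gene number the p was 0.13 in the exact binomial test, which does not show equality, and the same expectation left chromosome V at 0.667 and III at 1.48. Gene number alone does not account for the strong peaks, where X held 0.746 of its share by genes (exact binomial p = 2.1e-06). Loss of weak X peaks at the threshold stays open: among the stronger 2070 peaks X held 0.578 of its share by span, but a general lowering of strength on X would reduce strong peaks and lose weak ones alike. Lower binding on X or a lower yield of its chromatin also stays open, since no read counts were used here and no biological explanation was tested.

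The close spacing was weighed against 2 explanations. Splitting of broad bound regions by the peak caller could give close neighbours. After regions within 1 kb were merged, 824 neighbouring midpoints still lay within 5 kb, above the highest of 1000 uniform placements, 774. This count takes in pairs 2 to 5 kb apart, of which there were 653 before merging, and uniform placement keeps no regional density. It cannot tell whether splitting gave the excess within 2 kb, since merging itself removes such pairs. Splits at gaps wider than 1 kb also remain possible. Uneven density on a scale of 100 kb did not give the whole excess. Placements that kept the count of every 100 kb window gave 384 pairs within 2 kb on average and at most 445. Observed were 455, and uniform placement gave 344. The counts kept include the close pairs themselves, so how much of the excess comes from uneven density cannot be told. Binding at both ends of short genes or at closely spaced promoters was not tested.

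The difference between the arms of chromosomes II and IV prompted a hypothesis. In this species each chromosome has its meiotic pairing centre near one end. For the test it was taken to lie on the right of I, II and III and on the left of IV, V and X. This assignment was not checked here and is in doubt for II, III and V. The outer section taken as the pairing-centre arm held more peaks on 4 of the 6 chromosomes. These were II (1.75-fold), III (1.20-fold), IV (1.47-fold) and V (1.15-fold). That section held fewer on I (0.906) and X (0.824). The hypothesis was that the pairing-centre arm holds more peaks. On the arms taken, the exact sign test gave a two-sided p = 0.69, where the smallest possible with 6 chromosomes is 0.031. Neither exception passed its own exact binomial test (adjusted p = 0.32 and 0.11). With the other arm taken on II, III and V, each of these would count against the hypothesis. On II that arm would hold 139 peaks against 243 (exact binomial test, adjusted p = 6.9e-07), and under that assignment this difference would argue against it. Because the test depends on the arms taken, it cannot decide the hypothesis, which was not settled.

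The rank correlation of strength between neighbours within 2 kb was 0.0519 (455 pairs, not independent), against a mean of 0.0522 in 1000 shuffles within 100 kb windows (permutation p = 0.51). Distance classes were compared with another shuffle, not confined to 100 kb windows. Of 7 classes only neighbours 2 to 5 kb apart passed, with a rank correlation of 0.16 against a shuffled mean of 0.0109 (653 pairs, adjusted permutation p = 0.007). The shuffle within 100 kb windows covered only neighbours within 2 kb, so regional likeness was not removed from this class.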
